A study of Mus musculus with 12 samples.

How the data were processed

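The 12 libraries cover 4 tissues (brain, spinal cord, cranial dura, spinal dura) at 3 stages (naive, EAE onset, EAE peak), with 1 library for each of the 12 groups, taken from the library names. Per the labels' protocols, mice were perfused, the tissues were digested with enzymes, brain and spinal cord were also cleared of myelin, and live CD45+ and CD31+ cells were sorted at about 1:1 to 3:1 for 10x Genomics libraries read on an Illumina NovaSeq. The deposited values are raw UMI counts per gene and barcode. Per the submitters' processing notes, Cell Ranger 6.0, Seurat 4.0.4 and the mm10 build were used. Per the file headers, the spinal cord counts came from Cell Ranger 3.1.0 with 31053 genes, those of brain and spinal dura from 6.0.0 and those of cranial dura from 6.0.1, each with 32285 genes. This version follows the tissue, so a tissue difference may hold a software difference, whereas stage differences within a tissue do not. The 30406 gene IDs listed for all 12 libraries were used, which hold 99.51% to 99.95% of the UMIs of a library, and genes are given by the symbols that the feature lists pair with those IDs. Serpina3f, Serpina3g, Serpina3n, Ccl21a, Iigp1 and the H2 genes have near-identical relatives, so their single-gene counts are uncertain.

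The total per library was 101542857, 114153706 and 103702908 UMIs in brain (naive, onset, peak), 68694352, 106133348 and 89684935 in spinal cord, 45234186, 86719045 and 73866730 in cranial dura, and 25878049, 53228369 and 81482020 in spinal dura. Of 106450 barcodes, 94655 had at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. In the naive spinal dura library 1878 of 5158 barcodes were above 10% mitochondrial UMIs. Doublets were scored per library against simulated doublets, and the top-scoring 0.8% per 1000 barcodes were removed, 7084 in all, a fixed rate, leaving 87571 cells. Counts were scaled to 10000 per cell and log-transformed, and cells of all libraries were clustered together on 2000 variable genes and 30 principal components with 15 neighbours and the Leiden method at resolution 1, without batch integration, into 49 clusters (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2). Figures were drawn with matplotlib 3.10.9.

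Clusters were named only as similar to a cell type, written "-like" at first use, from marker lists fixed before the data were examined. The way the markers were scored was set after the clusters were seen: at least 3 markers, each in at least 10% of the cells and at 25% or more of the 95th percentile of its cluster means, and no more markers of another class than of its own among the 10 leading genes. Of the 49 clusters 8 stayed unnamed. Of these, 6 clusters with 12077 cells consist mainly of barcodes found in 3 or more libraries, a rule (over 50% of the cells) that was also set after seeing the data. They are led by genes such as Rbp7, Plvap, Ackr4, Marco and Ccl21a and take 21.8%, 22.7% and 18.2% of the cells of brain (naive, onset, peak), 35.8%, 24.1% and 26.5% of cranial dura, and at most 0.152% of the other libraries. The 2 other unnamed clusters take 5.96%, 5.41% and 4.42% in brain, 4.94%, 2.79% and 1.34% in spinal cord, at most 0.08% in cranial dura, and 3.74%, 0.374% and 0.41% in spinal dura. No deposited cell annotation was used.

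Counts were summed per library over the cells of a class, and a library entered a class with at least 20 cells. The sums were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test, 2-sided) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. Stages were compared with the tissue as a block, and stage by compartment as an interaction. Dural tissues were compared with brain and spinal cord in a model of tissue and stage, as a difference of tissue means. In that comparison the stages act as repeats, and the spread between the 2 tissues of a compartment is not part of the error. Microglia were tested in brain and spinal cord only. Errors are standard errors of the log2 fold change, and CPM values are UMI counts scaled in the usual way by the total of the class in the library, with TMM-scaled totals except within a tissue, where the plain totals of the class were used. For 20 gene lists fixed before the data were examined, each member was also adjusted over the list alone, and the lists were tested with camera (limma 3.58.1, preset correlation 0.01 and again with an estimated correlation). No list call with camera held at an adjusted p of 0.05 with an estimated correlation. The lists were leukocyte adhesion, interferon response, MHC class I, MHC class II, chemokines, blood-brain barrier, endothelial Wnt targets, fenestrated vessel, acute phase and NF-kB, basement membrane, cell cycle, dissociation immediate early, glycolysis, immune transcripts, homeostatic microglia, disease-associated microglia, border macrophage identity, inflammatory macrophage, T cell effector and naive T cell. Within a tissue there is no repeat, so those differences are given as values with no test.

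Genes were named by a rule fixed before the data were examined: up to 12 per direction with the largest change among those past the threshold with the same sign in every tissue and a mean of at least 20 CPM, up to 4 examples per list, and within a tissue the 8 largest and 8 smallest ratios among genes with at least 100 counts in the 2 libraries and 50 CPM in one. Mitochondrial, ribosomal, hemoglobin, predicted, immunoglobulin and T cell receptor genes were left out, and markers of other classes were counted as a carry-over group, except those that the tested class also uses, a detail set after seeing the data. Some genes that the rule names are not reported here. Where a group had 0 counts the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts the ratio is given with a 95% counting interval.

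Immune shares are percent of the immune cells of a library with 95% exact Clopper-Pearson intervals. Ratios of stages were averaged over tissues and tested with an exact sign-flip permutation test, 2-sided. A count of 0 was set to 3 cells in ratios, a choice made after seeing the data, with 0.5 cells added to each count as the alternative. A share of 0 allows up to 3 cells of the total. Intervals and limits cover counting error only.

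The scripts were tested on simulated data drawn from the real means with 200 changed genes. Of genes changed 2-fold the test recovered 59% and 60% in endothelium at onset and peak and 69% in dura against brain and spinal cord. For endothelial peak against onset it was 66%. It was 42% and 55% in border macrophages, 7% and 1% in microglia, 1% and 3% in neutrophils and 4% and 3% in the interactions. Camera with an estimated correlation missed a list raised 2-fold in the microglia and neutrophil comparisons. Of genes changed 4-fold the test recovered 84% and 89% in the endothelial comparisons of onset and peak, 88% in dura against brain and spinal cord, 87% for peak against onset, 59% in both microglia comparisons, 93% and 92% in border macrophages, 13% and 26% in neutrophils, and 50% and 57% in the interactions at onset and peak. The alternatives fixed before the data were examined were RLE normalization, DESeq2 1.42.0, no low-count filter, a mean of at least 20 CPM, no doublet removal, at most 5% mitochondrial UMIs, at least 1000 UMIs, Leiden resolution 0.5, thinning to the shallowest library, leaving out each tissue (or stage), no tissue block, and endothelial cells with no UMI of 4 immune genes. Those chosen after seeing the data were leaving out shared barcodes, counting the clusters of shared barcodes as endothelial, leaving out endothelial sub-clusters led by markers of other classes, leaving out the cluster with most naive spinal dura endothelial cells, and the test of spinal against cranial tissues.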

Results

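The data are 12 droplet-based single-cell RNA sequencing libraries from C57Bl/6J mice. Immune cells, sorted as CD45+, and endothelial cells, sorted as CD31+, were collected from brain, spinal cord, cranial dura and spinal dura. Each tissue was taken from naive mice, from mice at the onset of experimental autoimmune encephalomyelitis (EAE) and from mice at its peak. EAE is a mouse model of multiple sclerosis, here started by immunization with a peptide of myelin oligodendrocyte glycoprotein, and the library names place onset at day 10 and peak at day 14. Each of the 12 combinations of tissue and stage was 1 library, so no tissue had a repeat at any stage. The libraries held 25878049 UMIs (spinal dura, naive) to 114153706 UMIs (brain, onset) in 106450 barcodes, of which 87571 cells were used. The number of cells used per library ranged from 3125 (spinal dura, naive) to 9546 (brain, peak), with a median of 3149 (cranial dura, naive) to 10253 UMIs per cell (spinal cord, onset). The comparisons asked how the vascular and immune cells of the nervous system and of its meningeal border differed between stages, and how the endothelium of the dura differed from that of brain and spinal cord. In the gene tests the 4 tissues stood in for repeats of a stage, so the p-values measured how a stage difference varied from tissue to tissue. They do not measure the spread between animals, and whether several tissues came from the same mice is not given.

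The first comparison was of the immune cells in each tissue across the stages. In the naive brain and spinal cord the immune cells were almost all microglia-like, the resident macrophages of the parenchyma, at 89.8% (95% exact Clopper-Pearson interval 88.4 to 91.0) and 89.4% (88.1 to 90.7). In spinal cord this share was 4.49% at onset (3.87 to 5.18) and 7.87% at peak (7.03 to 8.77), and in brain it was 65.1% (62.8 to 67.3) and 31.4% (29.6 to 33.3). Monocyte-like cells made up 0.939% of the immune cells of the naive spinal cord (0.575 to 1.45) and 64.2% at onset (62.7 to 65.7). In brain the highest share was at peak, at 42.7% (40.8 to 44.7). It was 12.9% at onset (11.4 to 14.6) and 0.193% in the naive library (0.0526 to 0.494). In spinal cord at onset 2317 of these cells fell in a cluster led by genes such as Gpnmb, Arg1 and Spp1. Another 225 fell in a cluster led by genes such as Nos2 and Inhba. Neither cluster had a monocyte marker among its 10 leading genes. T cell-like cells were 0.193%, 1.11% and 5.90% of the immune cells of brain at the naive, onset and peak stages, 0.329%, 11.7% and 10.9% in spinal cord, 5.15%, 16.3% and 20.8% in spinal dura, and 7.91%, 5.44% and 9.18% in cranial dura. Intervals cover counting error only. The sort set the ratio of immune to endothelial cells, so all shares were taken among immune cells.

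Neutrophil-like cells were not seen in the naive brain (0 of 2072 immune cells, which allows a share of up to 0.145%) and were 4.25% and 3.07% of the immune cells of brain at onset and peak. Their share was 0.423%, 10.8% and 28.9% in spinal cord, 12.5%, 25.9% and 28.6% in cranial dura, and 2.94%, 32.6% and 13.3% in spinal dura. Border macrophage-like cells, the macrophages of meninges and perivascular spaces, held 48.0% of the immune cells of the naive spinal dura (43.1 to 53.0), 3.47% at onset (2.93 to 4.07) and 5.09% at peak (4.51 to 5.71). In cranial dura their share was 18.3%, 16.5% and 17.9%. B cell-like cells were 14.9% of the immune cells of the naive cranial dura (13.6 to 16.2), 1.61% at onset (1.29 to 2.0) and 2.69% at peak (2.24 to 3.20). Microglia-like cells also made up 11.8% of the 408 immune cells of the naive spinal dura (8.80 to 15.3), against 0.607% and 0.378% at onset and peak, while the cranial dura libraries held at most 0.264%.

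Over the 4 tissues the mean log2 ratio of the peak share to the naive share was 3.98 ± 3.29 for monocytes, 3.47 ± 2.21 for neutrophils and 3.06 ± 2.36 for T cells (SD, n = 4 tissues). Each of these 3 ratios was above 0 in all 4 tissues (exact sign-flip permutation test, 2-sided p = 0.13, which is the smallest p that 4 tissues allow). At onset the ratio was 3.78 ± 2.66 for monocytes and 3.52 ± 1.76 for neutrophils, higher in all 4 tissues (exact p = 0.13), and 2.20 ± 2.35 for T cells, higher in 3 of 4 (exact p = 0.25). For border macrophages the ratio at peak was -1.81 ± 1.83 and below 0 in all 4 tissues (exact p = 0.13). At onset it was -1.90 ± 2.37, above 0 in 1 of 4 tissues (exact p = 0.375). The B cell ratio was -1.0 ± 2.29 at onset and -0.35 ± 2.29 at peak, above 0 in 2 of 4 tissues each time (exact p = 0.5 and 0.875). In the 2 tissues that hold microglia their ratio was -2.39 ± 2.72 at onset and -2.51 ± 1.41 at peak, where the smallest exact p is 0.5. None of these tests could pass 0.05.

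**Figure D1:**
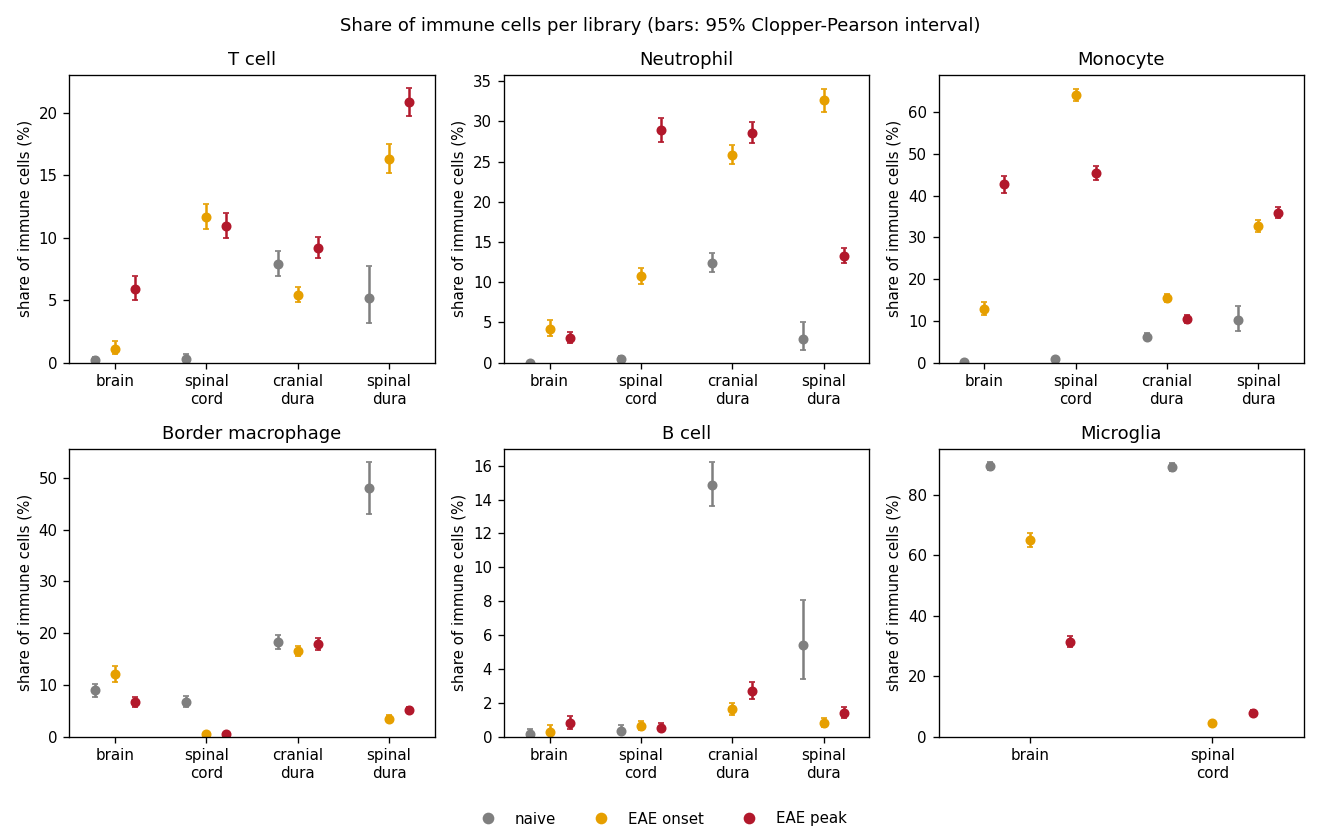
Share of each cell class among the immune cells of a library in percent (vertical axis), by tissue and stage (horizontal axis), with 95% exact Clopper-Pearson bars that cover counting error only. Monocytes reach 64.2% in spinal cord at onset and 42.7% in brain at peak, and border macrophages go from 48.0% in the naive spinal dura to 3.47% at onset.

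In endothelial-like cells the comparison of onset with naive libraries found genes of the acute phase, of complement and of leukocyte recruitment among those with the largest increases. Of 14646 genes tested, 714 rose and 342 fell (edgeR quasi-likelihood test, adjusted p below 0.05), and 1028 of these 1056 moved in the same direction in every tissue. Lcn2, which encodes the iron-sequestering acute phase protein lipocalin 2, rose by 6.65 ± 1.02 on the log2 scale (SE, n = 4 tissues, adjusted p = 0.00878), from 10.99 to 3445 CPM in brain and from 205 to 12486 CPM in spinal dura. The complement genes C3 and C1s1 rose by 7.29 ± 0.56 and 6.37 ± 0.36. Csf3, the granulocyte colony-stimulating factor, had 0 counts over the 4 naive libraries and 1681 at onset, at least 534-fold higher against 3 counts over the group. Slc22a8, the organic anion transporter of brain capillaries, fell by 2.13 ± 0.44. Other genes with large increases were the ubiquitin-like modifier Ubd (10.71 ± 1.27), the interferon-gamma-inducible chemokine Cxcl9 (6.99 ± 1.44), AA467197 (6.85 ± 0.65), Acat3 (7.53 ± 0.56), Tnfsf8 (6.30 ± 0.54) and Glycam1 (8.12 ± 2.08), the selectin ligand of high endothelial venules. Itih4 had 3 counts over the naive libraries and a ratio of 1356 (95% counting interval 464 to 6579). Among the genes that fell were Ptn (-2.06 ± 0.36), Bche (-2.13 ± 0.33), the vasoactive peptide gene Edn3 (-1.87 ± 0.44), the carbonic anhydrase gene Car4 (-1.80 ± 0.35), Sgpp2 (-1.86 ± 0.34) and the lymphangiogenic factor Vegfc (-1.62 log2).

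Of the 17 measured leukocyte adhesion genes, 7 rose and 0 fell at onset (8 rose when adjusted over the list alone). They included Sele (6.61 ± 1.07) and Selp (5.98 ± 1.02), the selectins that slow rolling leukocytes, the venular chemokine receptor Ackr1 (5.69 ± 0.87) and Icam1 (2.06 ± 0.25). The list ranked above other genes (camera adjusted p = 0.000148, and adjusted p = 0.186 with an estimated correlation). Chemokine genes rose in 7 of 15 cases and fell in 0 (9 adjusted over the list alone), among them Ccl21a (5.38 ± 0.94), Cxcl1 (5.10 ± 0.57) and Ccl19 (4.23 ± 0.71), with camera adjusted p = 2.62e-05 and adjusted p = 0.149 with an estimated correlation. In the acute phase and NF-kB list 9 of 16 rose and 0 fell (15 adjusted over the list alone), with Timp1 at 4.41 ± 0.56 and Lrg1 at 3.60 ± 0.90 (camera adjusted p = 3.54e-11, and adjusted p = 0.186 with an estimated correlation). Cell cycle genes rose in 11 of 12 cases, such as Birc5 (5.01 ± 0.71), Top2a (4.19 ± 0.56) and Mki67 (4.15 ± 0.68). That list had a camera adjusted p = 4.85e-09, and adjusted p = 0.24 with an estimated correlation. MHC class II genes, which present antigen to CD4 T cells, rose in 3 of 7 cases (7 adjusted over the list alone), with Cd74 at 2.76 ± 0.68 and the class II transactivator Ciita at 2.31 ± 0.41, with camera adjusted p = 2.62e-05, and adjusted p = 0.24 with an estimated correlation. Of 14 MHC class I genes 5 rose, including Tap1 at 1.04 ± 0.23 (camera adjusted p = 1.33e-05, and adjusted p = 0.24 with an estimated correlation).

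Of 22 blood-brain barrier genes, 5 fell and 1 rose at onset (13 fell and 1 rose adjusted over the list alone). The fallen ones included Slc22a8, the proteoglycan gene Spock2 (-1.39 ± 0.33), the monocarboxylate transporter Slc16a1 (-1.17 ± 0.27) and the arginine transporter Slc7a1 (-1.13 ± 0.28), with camera adjusted p = 0.000168, and adjusted p = 0.353 with an estimated correlation. Of 12 endothelial Wnt target genes 2 fell, Nkd1 (-1.01 ± 0.19) and Sox17 (-0.59 ± 0.15), and 10 fell adjusted over the list alone (camera adjusted p = 4.78e-05, and adjusted p = 0.24 with an estimated correlation). Transcripts of other cell types moved too. Of 15 immune transcripts used as a marker of carry-over, 6 rose and 1 fell. S100a8 rose by 4.31 ± 0.86 and Lyz2 by 2.44 ± 0.62. Among 140 markers of other cell classes 27 rose and 10 fell. The fibroblast gene Dcn rose by 3.58 ± 0.70, but it was also among the 10 leading genes of an endothelial sub-cluster, with Itih4, Ubd and Selp. In spinal dura 1 cluster held 1894 of the 2291 naive endothelial cells and in spinal cord another held 2564 of 3917, while other clusters held most of them at onset and peak. The count of 1056 was 111 without spinal dura, 296 without spinal cord, 490 without brain and 776 without cranial dura, and 142 when the clusters with barcodes shared between brain and cranial dura libraries were counted as endothelial. Of the 74 genes named for this comparison that passed the test, 60 no longer passed in at least 1 of these left-out fits.

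At the peak of EAE the endothelial comparison with naive libraries gave 774 genes that rose and 409 that fell, 1142 of the 1183 in the same direction in all 4 tissues. Lcn2 rose by 6.95 ± 1.08 on the log2 scale (SE, n = 4 tissues, edgeR adjusted p = 0.00839), C3 by 7.37 ± 0.56 and the acute phase serpin Serpina3n by 7.24 ± 1.21. Cxcl9 rose by 9.22 ± 1.42, from 0.23 to 55.4 CPM in brain and from 0.77 to 657 CPM in spinal dura, and Ubd by 12.36 ± 1.24. Csf3 was at least 2027-fold higher than 3 counts over the naive group. The anion transporter Slc22a8 fell by 2.29 ± 0.45 (adjusted p = 0.0206), in spinal cord from 407 to 73.6 CPM and in spinal dura from 284 to 21.6 CPM. Acat3 (7.22 ± 0.56), AA467197 (7.42 ± 0.64), C1s1 (6.28 ± 0.35) and Tnfsf8 (5.89 ± 0.54) were also among the 12 with the largest increases. Itih4 had a ratio of 2994 (counting interval 1024 to 14520), and Glycam1 reached 9.28 ± 2.06 through uneven log2 changes of 1.88 in brain, 7.71 in spinal cord, 0.13 in cranial dura and 11.87 in spinal dura. Bche (-2.27 ± 0.33), Ptn (-2.13 ± 0.37), Edn3 (-2.13 ± 0.45), the alkaline phosphatase gene Alpl (-1.90 ± 0.44), Car4 (-1.80 ± 0.35), Pomc (-1.64 log2) and the iron exporter Slc40a1 (-1.62 log2) fell.

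**Figure D2:**
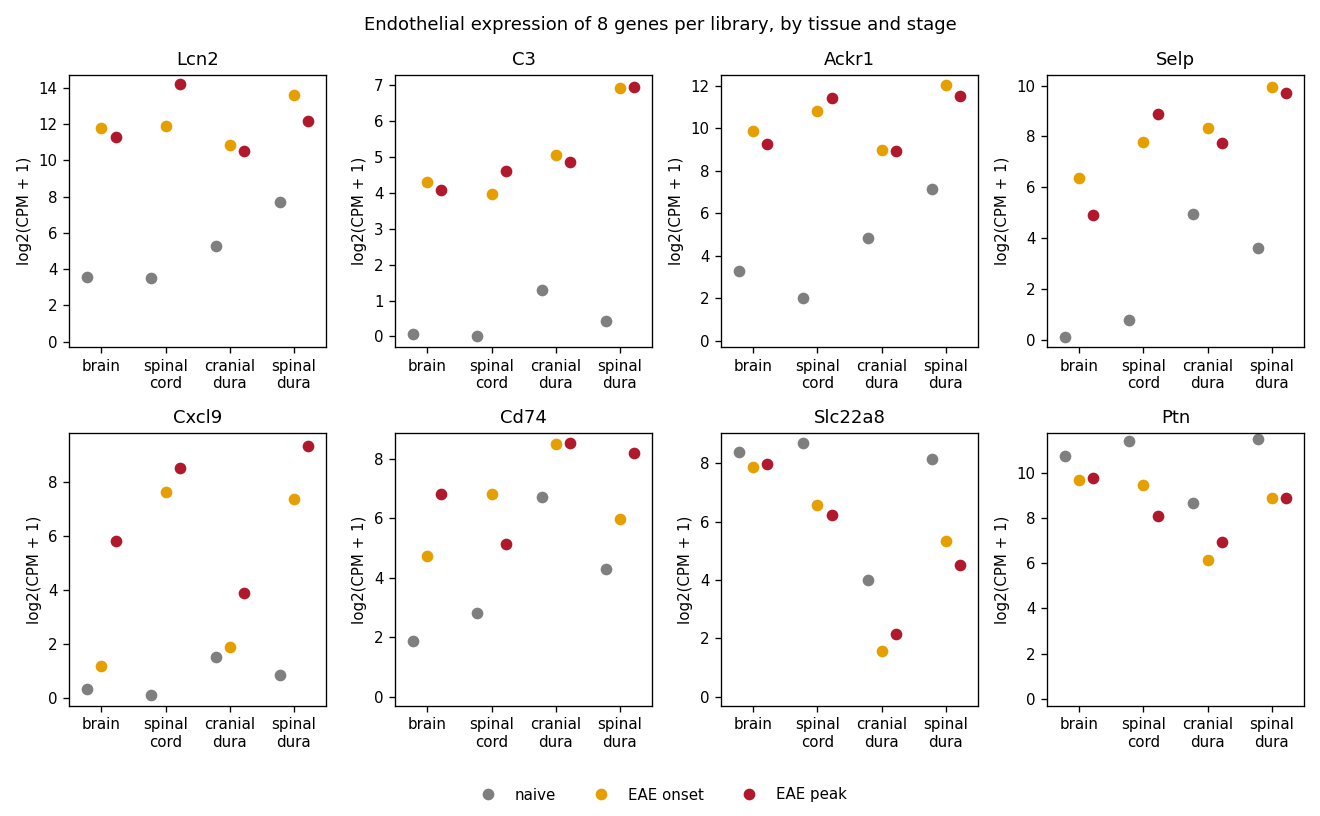
Endothelial level of 8 genes per library as log2(CPM + 1) (vertical axis) by tissue (horizontal axis), with 1 point per stage, set apart by colour. There are no error bars because each point is 1 library. Lcn2 goes from 10.99 to 3445 CPM between naive and onset in brain, and Slc22a8 from 407 to 73.6 CPM between naive and peak in spinal cord.

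All 7 MHC class II genes rose at peak, including Cd74 (3.53 ± 0.71) and H2-Ab1 (2.99 ± 0.63), with camera adjusted p = 2.22e-06, and adjusted p = 0.206 with an estimated correlation. Cd74 was at 2.69, 25.3 and 112 CPM in brain at the 3 stages and at 104, 359 and 366 CPM in cranial dura. Of 14 MHC class I genes 5 rose and 0 fell (11 adjusted over the list alone), with H2-Q7 at 1.34 ± 0.30 (camera adjusted p = 3.93e-06, and adjusted p = 0.206 with an estimated correlation). Of 24 interferon response genes 7 rose, among them the GTPases Iigp1 (1.5 ± 0.28) and Gbp2 (1.36 ± 0.28), with camera adjusted p = 0.000921, and adjusted p = 0.347 with an estimated correlation. Of 15 chemokine genes 9 rose, including Ccl5 (4.98 ± 1.18) and Ccl19 (4.96 ± 0.70), with camera adjusted p = 3.03e-06, and adjusted p = 0.0928 with an estimated correlation. Of 17 adhesion genes 7 rose (8 adjusted over the list alone), such as Selp (5.78 ± 1.03), Ackr1 (5.62 ± 0.88) and Icam1 (1.86 ± 0.25), with camera adjusted p = 0.000534, and adjusted p = 0.205 with an estimated correlation. In the acute phase and NF-kB list 14 of 16 rose (16 adjusted over the list alone), including Timp1 (4.49 ± 0.57) and the cytokine Il6 (4.04 ± 0.73), with camera adjusted p = 2.81e-12, and adjusted p = 0.17 with an estimated correlation.

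Of 22 blood-brain barrier genes 5 fell and 0 rose at peak (9 fell adjusted over the list alone), among them Slc16a1 (-1.22 ± 0.27), Itm2a (-1.19 ± 0.21) and Slc7a1 (-1.10 ± 0.28), with camera adjusted p = 0.000498, and adjusted p = 0.347 with an estimated correlation. Of 12 Wnt target genes 4 fell, Axin2 (-0.96 ± 0.25), Nkd1 (-0.83 ± 0.18), Foxq1 (-0.69 ± 0.18) and Sox17 (-0.57 ± 0.15), and 11 fell adjusted over the list alone (camera adjusted p = 5.89e-05, and adjusted p = 0.206 with an estimated correlation). Of 10 fenestrated vessel genes 1 rose, the fatty acid receptor Cd36 (1.20 ± 0.30), and 3 rose adjusted over the list alone (camera adjusted p = 0.0871). Basement membrane genes passed in 0 of 11 cases (5 rose adjusted over the list alone), with camera adjusted p = 0.0109, and adjusted p = 0.206 with an estimated correlation. Of 12 cell cycle genes 5 rose, such as Birc5 (4.15 ± 0.73), and 12 adjusted over the list alone (camera adjusted p = 1.17e-06, and adjusted p = 0.206 with an estimated correlation). Of 12 glycolysis genes 4 rose, led by the lactate exporter Slc16a3 (2.72 ± 0.47), and 9 adjusted over the list alone (camera adjusted p = 3.99e-05, and adjusted p = 0.206 with an estimated correlation). Of 13 dissociation-induced immediate early genes 1 rose, Ier3 (1.57 ± 0.25), with camera adjusted p = 0.365.

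Lists named for other cell types also moved within the endothelial class at peak. Of 15 immune transcripts used as a marker of carry-over 7 rose and 1 fell, with S100a8 at 3.47 ± 0.81 and the T cell receptor gene Trbc2 at 2.81 ± 0.71 (camera adjusted p = 0.00365, and adjusted p = 0.206 with an estimated correlation). Of 14 inflammatory macrophage genes 10 rose, including Il1rn (6.36 ± 0.72), Arg1 (5.76 ± 0.80) and Cd14 (5.17 ± 0.51), with camera adjusted p = 4.02e-08, and adjusted p = 0.17 with an estimated correlation. Of 19 genes of the disease-associated microglia list 9 rose, with Lgals3 at 2.94 ± 0.41 (camera adjusted p = 1.44e-07, and adjusted p = 0.17 with an estimated correlation), and of 14 homeostatic microglia genes 2 fell, Gpr34 (-2.75 ± 0.63) and P2ry12 (-2.71 ± 0.64), with camera adjusted p = 0.000779, and adjusted p = 0.351 with an estimated correlation. Of 11 border macrophage identity genes 1 fell, Gas6 (-1.54 ± 0.31), with camera adjusted p = 0.942. Of 7 T cell effector genes 3 rose, among them Il2ra (2.20 ± 0.48) and Icos (1.82 ± 0.49), with camera adjusted p = 0.000498, and adjusted p = 0.17 with an estimated correlation. Of 7 naive T cell genes 2 rose, Ccr7 (3.73 ± 0.76) and Il7r (2.98 ± 0.67), with camera adjusted p = 0.39. The count of 1183 was 106 without spinal dura, 290 without spinal cord, 647 without brain and 886 without cranial dura, 170 with the clusters of shared barcodes counted as endothelial, and 773 in cells with no UMI of Ptprc, Tyrobp, Cd3e and Cd79a. Of the 83 named genes that passed, 70 no longer passed in at least 1 left-out fit.

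**Figure D3:**
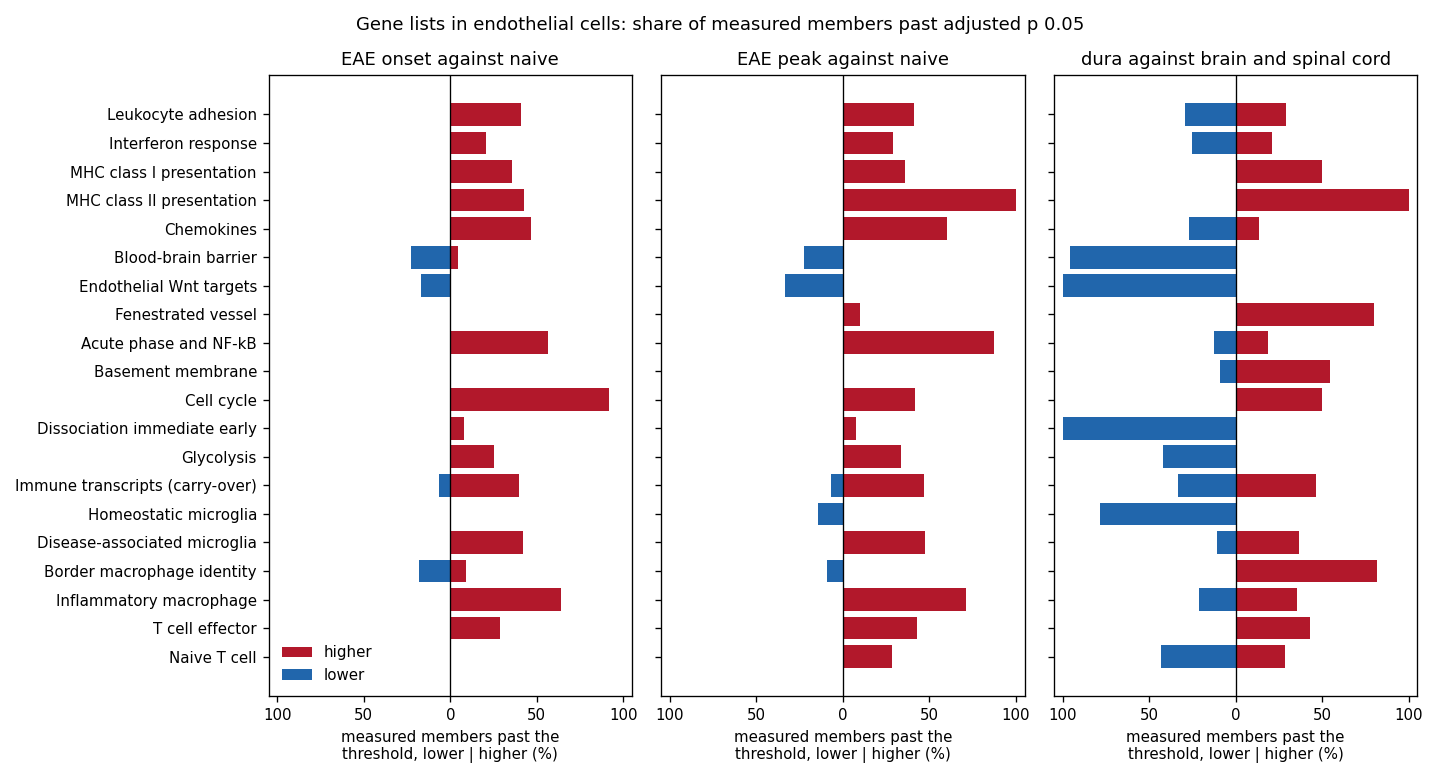
Percent of the measured members of each gene list that passed the edgeR test at adjusted p below 0.05 in endothelial cells, lower members to the left and higher members to the right of 0, for onset against naive, peak against naive, and dura against brain and spinal cord. At peak 7 of 7 MHC class II and 14 of 16 acute phase and NF-kB genes were higher, and in dura 21 of 22 blood-brain barrier genes were lower.

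Peak and onset were also compared with each other in endothelial cells. edgeR called 0 genes, with 211 at an unadjusted p below 0.05, and DESeq2 called 3. No member of any of the 20 lists passed the test over all genes. The median of the 12 cell cycle genes was 0.84 lower on the log2 scale at peak than at onset (median log2 change -0.84, camera adjusted p = 0.000105), and adjusted p = 0.814 with an estimated correlation. For the 7 MHC class II genes the median log2 change was 0.60 (camera adjusted p = 0.0404, and adjusted p = 0.814 with an estimated correlation).

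The endothelium of the 2 dural tissues differed from that of brain and spinal cord in genes of vessel type. Aqp1, a water channel of peripheral endothelium, was higher in dura by 7.64 ± 0.44 on the log2 scale (SE, n = 3 stages, edgeR adjusted p = 2.35e-06), at 429 to 621 CPM in cranial dura and 9.28 to 61.6 CPM in spinal dura against at most 1.5 CPM in brain and spinal cord. Cd36 (7.24 ± 0.29), Gpihbp1 (6.08 ± 0.47), which anchors lipoprotein lipase to capillaries, and the fatty acid binding protein gene Fabp4 (5.34 ± 0.32) were higher as well. The thyroid hormone transporter Slco1c1 (-4.43 ± 0.36), the lipid transporter Mfsd2a (-4.15 ± 0.25) and the secreted Wnt inhibitor Notum (-3.90 ± 0.44) were lower in dura. With 3770 genes higher and 3718 lower, 7488 of 14646 genes passed, 7418 with the same sign in every stage. These p-values leave out the spread between the 2 tissues of a compartment. In a model that counts that spread as error, 4296 genes passed. That model takes the 3 libraries of a tissue as independent, although each compartment has 2 tissues, so its p-values may also be too small. Further genes higher in dura were Penk (6.20 ± 0.94), Btnl9 (5.42 ± 0.48), Col13a1 (5.38 ± 0.50), Enpp6 (5.37 ± 0.45), Igfbp5 (5.22 ± 0.49), Wipf3 (5.29 ± 0.29) and the retinol binding protein gene Rbp7 (5.01 ± 0.64). Further genes lower in dura were Ddc (-4.90 ± 0.33), Car5a (-4.15 ± 0.18), the glutamate transporter Slc1a1 (-3.99 ± 0.18) and the reelin receptor Lrp8 (-3.79 ± 0.21).

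Of 22 blood-brain barrier genes 21 were lower in dura and 0 higher, with Slc22a8 at -3.48 ± 0.38 and Spock2 at -3.24 ± 0.28 (camera adjusted p = 7.61e-11, and adjusted p = 0.316 with an estimated correlation). All 12 Wnt target genes were lower, such as Nkd1 (-2.92 ± 0.16) and Tcf7 (-2.71 ± 0.27), with camera adjusted p = 1.25e-07, and adjusted p = 0.316 with an estimated correlation. Of 10 fenestrated vessel genes 8 were higher and 0 lower (camera adjusted p = 8.14e-05, and adjusted p = 0.0819 with an estimated correlation). The dural tissues were not alike. Plvap, the diaphragm protein of fenestrated vessels, was at 1320 to 1495 CPM in cranial dura but 21.6 to 57.5 CPM in spinal dura, close to the 23.2 to 32.8 CPM of brain. Slco1c1 was at most 13.7 CPM in cranial dura and 229 to 740 CPM in spinal dura. Endothelial clusters made up mostly of brain or spinal cord cells held 150, 99 and 58 naive spinal dura cells, against 4, 4 and 2 of naive cranial dura. Whether vessels of brain or spinal cord in the spinal dura libraries account for these levels was not tested. The median log2 difference of the barrier list was -2.04 with all tissues, -0.67 without cranial dura and -3.30 without spinal dura, and that of the fenestrated list was 4.62 and 2.36 without cranial dura. For the Wnt target list it was -2.06 with all tissues, -1.045 without cranial dura and -3.55 without spinal dura. The count of 7488 was 3774 without cranial dura, 4588 without the onset libraries and 4187 with a mean of at least 20 CPM.

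**Figure D4:**
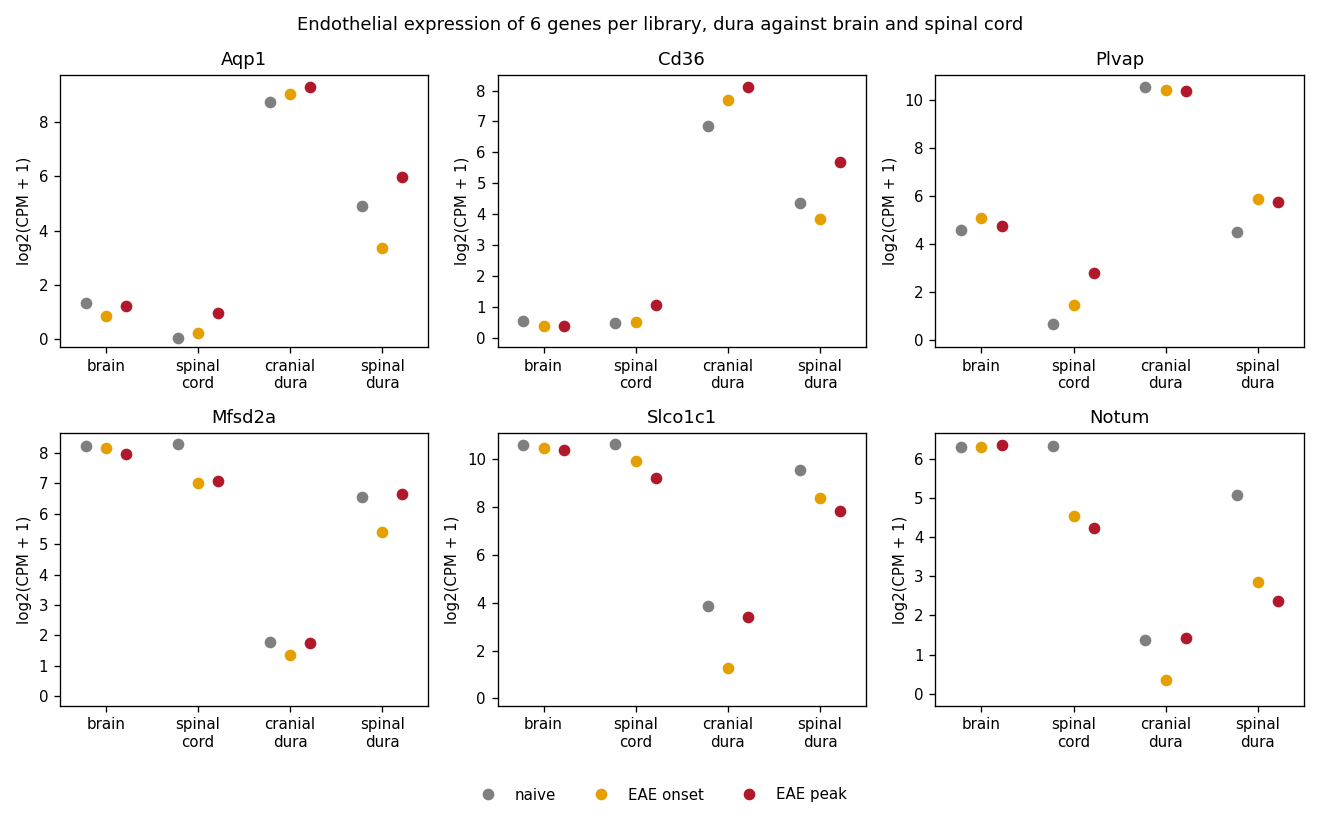
Endothelial level of 6 genes per library as log2(CPM + 1) (vertical axis) by tissue (horizontal axis), with 1 point per stage and no error bars because each point is 1 library. Plvap is at 1320 to 1495 CPM in cranial dura and 21.6 to 57.5 CPM in spinal dura, and Slco1c1 at most at 13.7 CPM in cranial dura and 229 to 740 CPM in spinal dura.

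Genes tied to other cell states differed between dura and parenchyma as well. All 7 MHC class II genes were higher in dural endothelium, with Ciita at 2.84 ± 0.32 and Cd74 at 2.28 ± 0.54 (camera adjusted p = 0.00434, and adjusted p = 0.559 with an estimated correlation). Of 11 basement membrane genes 6 were higher, such as the laminin gene Lamb1 (3.53 ± 0.44), and Fn1 was lower (-1.45 ± 0.21). All 13 immediate early genes that tissue dissociation induces were lower in dura, with the heat shock gene Hspa1a at -3.31 ± 0.23 and Fos at -1.57 ± 0.27 (camera adjusted p = 2.01e-05, and adjusted p = 0.559 with an estimated correlation). The labels give different dissociation steps for dura and for brain and spinal cord. Of 11 border macrophage genes 9 were higher in dura, with Mrc1 at 3.37 ± 0.36 (camera adjusted p = 0.000606, and adjusted p = 0.316 with an estimated correlation), and of 14 homeostatic microglia genes 11 were lower (camera adjusted p = 0.000877, and adjusted p = 0.559 with an estimated correlation). Among 140 markers of other cell classes 68 were higher and 28 lower. The spinal cord files were made with another version of the counting software, so that version and the tissue cannot be told apart.

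Whether the stage changes themselves differed between dural endothelium and that of brain and spinal cord was tested as an interaction. At onset edgeR called 0 genes, with 596 at an unadjusted p below 0.05, and DESeq2 called 35. At peak edgeR called 2 genes, with 772 at an unadjusted p below 0.05, and DESeq2 called 51. In simulated data the edgeR test recovered 4% of 2-fold changes at onset and 3% at peak, so few calls do not show equal changes. Serpina3f, a serine protease inhibitor gene, had a smaller increase in dura by 4.03 ± 0.30 on the log2 scale (interaction -4.03, SE, adjusted p = 0.0137). It went from 0.12 to 24.1 CPM in brain and from 0.4 to 134 CPM in spinal cord. In cranial dura it went from 1.43 to 28.5 CPM and in spinal dura from 5.74 to 94.4 CPM. Its levels at peak overlapped between the compartments, so the difference lay in the naive libraries, which were lowest in brain and spinal cord. Fgl2, a fibrinogen-like protein with prothrombinase activity, had an interaction of -3.44 ± 0.32 (adjusted p = 0.0403). It was at 0.42 and 2.9 CPM in naive and peak brain, 0.61 and 6.57 CPM in spinal cord, 34.8 and 29.2 CPM in cranial dura, and 40.9 and 32.5 CPM in spinal dura. Its mean level was below the minimum set for naming a gene, and it was chosen after its values were seen. No list member passed over all genes. The acute phase and NF-kB list ranked below other genes in this difference at peak (camera adjusted p = 5.65e-06, and adjusted p = 0.862 with an estimated correlation). The count at peak was 20 without brain and 0 without spinal cord, without cranial dura or without spinal dura, and it was 0 in thinned libraries. At onset it was 10 without brain.

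Microglia were compared between stages in brain and spinal cord. At onset 70 of 11989 genes rose and 0 fell, and at peak 238 rose and 0 fell (edgeR, 2 tissues and 2 residual degrees of freedom). In simulated data this test recovered 7% and 1% of 2-fold changes, so moderate falls could be missed. Iigp1, an interferon-inducible GTPase, rose by 5.70 ± 0.66 on the log2 scale at onset and by 7.63 ± 0.72 at peak (SE, n = 2 tissues, adjusted p = 0.0117 at peak), from 0.76 to 266 CPM in brain and from 3.36 to 337 CPM in spinal cord. Acod1, which makes itaconate, rose by 5.97 ± 0.74 and 6.47 ± 0.77. Birc5, which encodes survivin, rose by 4.33 ± 0.62 and 5.61 ± 0.65. Other genes that rose at onset were Inhba (5.68 ± 0.64), Serpina3g (5.53 ± 0.84), Ifitm1 (5.86 ± 0.81) and the C-type lectin gene Clec4e (4.81 ± 0.73). At peak they included complement C4b (6.19 ± 1.07), Gbp4 (6.14 ± 0.61), Gbp2 (5.92 ± 0.67) and the cholesterol hydroxylase gene Ch25h (5.53 ± 0.52). In brain 1 cluster held most microglia at each stage (1696 of 1860, 933 of 1118 and 394 of 766). In spinal cord another cluster held 1546 of 1905 naive microglia, and 1 of 179 at onset and 15 of 299 at peak.

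Of 24 interferon response genes 3 rose in microglia at onset (20 adjusted over the list alone) and 16 at peak (22 adjusted over the list alone), with camera adjusted p = 7.53e-16 and 9.44e-19, and adjusted p = 0.395 and 0.404 with an estimated correlation. Of 12 cell cycle genes 8 rose at onset and 11 at peak, such as Rrm2 (5.41 ± 0.52 at peak), with camera adjusted p = 3.62e-17 and 6.98e-16, and adjusted p = 0.366 and 0.376 with an estimated correlation. At peak 4 of 12 chemokine genes rose, Cxcl10 (4.50 ± 0.71), Ccl7 (4.18 ± 0.60), Ccl12 (3.67 ± 0.64) and Ccl2 (2.45 ± 0.45), with camera adjusted p = 6.66e-06, and adjusted p = 0.376 with an estimated correlation. Of 14 inflammatory macrophage genes 4 rose at peak, among them the nitric oxide synthase Nos2 (5.03 ± 0.66) and the monocyte marker Plac8 (4.83 log2), with camera adjusted p = 1.33e-09, and adjusted p = 0.404 with an estimated correlation. Of 14 homeostatic microglia genes 0 passed in either comparison (6 fell at peak adjusted over the list alone). P2ry12, the purinergic receptor that marks resting microglia, had a log2 change of -2.24 ± 0.57 at peak (edgeR adjusted p = 0.114), from 2577 to 911 CPM in brain and from 1464 to 208 CPM in spinal cord. The list had a camera adjusted p = 8.51e-06, and adjusted p = 0.466 with an estimated correlation. MHC class II genes passed in 0 of 7 cases at peak (7 rose adjusted over the list alone), with H2-Aa at 5.63 ± 1.78 and an edgeR adjusted p of 0.182. Among 110 markers of other cell classes 6 rose at onset and 9 at peak. Inhba and Nos2, which rose in microglia, were also among the 10 leading genes of a monocyte cluster. Ifitm1 and Acod1 were among those of neutrophil clusters. Whether RNA or cells of those classes in the microglia account for these increases was not tested. Leaving out a tissue left no residual degrees of freedom, so no such fit was made, and the counts were 839 and 1533 with no filter on low counts, 24 and 65 with a mean of at least 20 CPM, and 413 and 932 with DESeq2.

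Border macrophages were compared over 11 libraries, because the spinal cord at onset held 16 of these cells, below the minimum of 20. Arg1, an arginine-degrading enzyme and marker of alternatively activated macrophages, rose by 6.21 ± 0.95 on the log2 scale at onset (edgeR adjusted p = 0.0121) and by 7.83 ± 0.85 at peak (SE, adjusted p = 0.00107). The acute phase gene Saa3 rose by 4.71 ± 0.62 and 6.51 ± 0.61, reaching 2336 CPM in spinal dura and 974 CPM in brain at peak. Retnla, a gene that interleukin 4 induces in macrophages, fell by 7.25 ± 0.99 at onset and by 4.19 ± 0.73 at peak, from 570 to 0 CPM in spinal dura and from 73.0 to 14.97 CPM in cranial dura. In all, 168 genes rose and 21 fell at onset and 373 rose and 203 fell at peak. F10, the gene of coagulation factor X, rose by 5.16 ± 0.84 and 5.80 ± 0.81, the angiogenic factor Vegfa by 3.82 ± 0.71 and 4.74 ± 0.64, and Clec4e by 3.86 ± 0.52 and 4.20 ± 0.50. Acod1 (5.03 ± 0.78 at peak), complement Cfb (4.56 ± 0.74), Ifitm1 (4.54 ± 0.50), Spon1 (4.49 ± 0.42) and Ly6a (4.21 ± 0.35) also rose. Mmp9 (-2.63 ± 0.40 and -3.01 ± 0.39), the scavenger receptor Cd36 (-2.27 ± 0.32 and -2.31 ± 0.29) and Slc40a1 (-1.32 ± 0.30 and -1.95 ± 0.27) fell at both stages. At peak the prostaglandin dehydrogenase Hpgd (-2.93 ± 0.48), the phospholipase gene Pla2g2d (-2.71 ± 0.44), Bmp2 (-2.55 ± 0.40), the lectin gene Mgl2 (-2.12 ± 0.55) and Ccl24 (-1.94 ± 0.46) fell.

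Of 24 interferon response genes 11 rose in border macrophages at onset and 20 at peak, such as Gbp2 (3.15 ± 0.67 at peak), with camera adjusted p = 9.09e-20 and 6.49e-17, and adjusted p = 0.223 and 0.22 with an estimated correlation. MHC class I genes rose in 4 of 14 cases at onset and 11 at peak, with Tap1 at 1.63 ± 0.27 and 1.90 ± 0.25, and 1 of 7 MHC class II genes rose at peak, Ciita (1.12 ± 0.28). For MHC class I the camera adjusted p was 9.12e-10 at onset and 1.04e-11 at peak, and adjusted p = 0.235 and 0.22 with an estimated correlation. Of 12 glycolysis genes 4 rose at onset and 8 at peak, including Slc16a3 (2.58 ± 0.46) and Pgk1 (2.15 ± 0.43), with camera adjusted p = 4.67e-08 and 3.95e-08, and adjusted p = 0.235 and 0.232 with an estimated correlation. Of 14 inflammatory macrophage genes 10 rose at each stage, among them Plac8 (5.55 ± 0.78 and 5.40 ± 0.75) and Fn1 (2.47 ± 0.42 and 3.26 ± 0.41), with camera adjusted p = 3.75e-10 and 1.1e-08, and adjusted p = 0.223 and 0.22 with an estimated correlation. Of 12 border macrophage identity genes 0 passed at onset and 2 fell at peak, Pf4 (-1.85 ± 0.42) and Maf (-1.20 ± 0.29), with camera adjusted p = 0.00165 at peak, and adjusted p = 0.535 with an estimated correlation. Of 19 disease-associated microglia genes 3 rose at peak, led by Gpnmb (5.56 ± 0.68) and Lgals3 (2.78 ± 0.48), with camera adjusted p = 0.00678, and adjusted p = 0.461 with an estimated correlation. Of 13 immediate early genes 5 fell at peak, such as Jun (-1.14 ± 0.19).

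Neutrophil transcripts were also found in the border macrophages. S100a8 rose by 3.77 ± 0.72 at onset and 3.25 ± 0.70 at peak, and among 93 markers of other cell classes 17 rose at onset and 17 rose and 9 fell at peak. Arg1, Gpnmb, Vegfa and F10, which rose in this class, were also among the 10 leading genes of monocyte clusters, as was Ccl24, which fell. Whether monocyte RNA or cells in the class account for those increases was not tested. In the EAE spinal dura libraries 1 cluster held most border macrophages (124 of 143 at onset and 239 of 269 at peak), as it did in spinal cord at peak (12 of 22), and another cluster held most of them in the other libraries tested. The former cluster had a median of 1392.5 UMIs per cell, while the medians of the libraries its cells came from averaged 6230.48. The count at onset was 11 without brain, 75 without spinal dura, 92 without spinal cord and 284 without cranial dura, against 189 with all tissues. At peak it was 33 without brain, 279 without spinal cord, 359 without spinal dura and 593 without cranial dura, against 576. Of the named genes that passed, 45 of 49 at onset and 57 of 68 at peak no longer passed in at least 1 of these fits.

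Neutrophils could be compared with 1 naive library alone, that of cranial dura, the only one with 20 or more of them (378 cells). The test assumes that it varies like the 8 others, so its p-values compare with that library and do not show a change of stage. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, had a log2 change of -4.22 ± 0.52 at onset (SE, edgeR adjusted p = 0.0237) and of -3.32 at peak (adjusted p = 0.151). Igfbp6 is a fibroblast marker of the carry-over group, but it was also among the 10 leading genes of a neutrophil cluster. It had a log2 change of 7.20 ± 0.73 at onset (edgeR adjusted p = 0.0069) and 6.69 ± 0.73 at peak (adjusted p = 0.0131). These were the 2 genes called at onset, with 501 at an unadjusted p below 0.05, and the 1 gene called at peak. The interferon response list ranked above other genes at both stages (camera adjusted p = 0.00538 and 2.6e-05), and adjusted p = 0.967 and 0.845 with an estimated correlation, with 0 members past the test over all genes. The chemokine genes Ccl2 and Cxcl1 had 0 naive counts and were at least 36.5-fold and at least 15.6-fold higher at onset against 3 counts over the group. These bounds set the pooled onset libraries of 4 tissues against the 1 naive library of cranial dura, so they mix tissue with stage. Neither of the 2 genes passed over all genes (edgeR adjusted p = 0.205 and 0.147), and both passed when adjusted over the list alone. The count at onset was 170 without spinal cord, 3 without spinal dura and 0 without brain, and at peak 91, 2 and 0, and DESeq2 called 33 and 21.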

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

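The tests of chance barcode reuse, of the degrees of freedom and of depth, the spinal against cranial test with its splits, and the comparison with splits that keep the tissues, were chosen only after the results were seen. The alternatives that leave out a cluster or count the clusters of shared barcodes as endothelial were also chosen then.

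In the brain and cranial dura libraries 1721 barcodes passed the filters in all 6 libraries, a signal outside the compared classes. The 15 pairs of these libraries share 1829 to 2202 barcodes and the 51 other pairs 5 to 50, so the lowest overlap is 36.58 times the highest of the other pairs, which argues against chance reuse of barcodes. Of 2122 such barcodes kept in 2 or more libraries, 96.7% had all copies in the 6 unnamed clusters. These clusters were picked by their share of such barcodes, so that percentage is largely fixed by the definition. Within them 97.3% of 27959 pairs of copies fell in the same cluster against 28.1% of random pairs, a ratio of 3.462. A candidate explanation is that cells of 1 outside preparation were read in several libraries, and no biological explanation was tested. Their leading genes include Ackr4, Marco, Ccl21a, Glycam1 and Chst4, known from lymph node vessels.

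Immune transcripts rose in the endothelial class at EAE. If RNA or cells of immune classes were carried into the class, a list's ratio of endothelial to immune CPM should stay within 2 times that of Tyrobp, Fcer1g and Lyz2. For the inflammatory macrophage list it did in all 8 EAE libraries, with a highest value of 1.791. Carry-over could therefore account for the rise of that list as a whole. The ratio is a median over the list, so it does not decide for single genes. For example, Cd14 was among the 10 leading genes of an endothelial sub-cluster that was also led by Csf3, Sele and Ackr1. For the MHC class II list the ratio was above 2 in 2 of 8 libraries, both of cranial dura (4.284 and 4.003), and 0.713 to 1.91 in the others, so expression by endothelial cells and carry-over cannot be told apart, because the libraries disagree. In cells with no UMI of 4 immune genes 773 genes passed at peak.

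Among the left-out tissues, the endothelial stage calls depended most on spinal dura, with 106 genes at peak without it against 1183. Different vessel beds in the naive and EAE spinal dura libraries stay open. Without the cluster that holds most naive spinal dura endothelial cells 994 genes passed at peak, but the clusters of the remaining cells still differed. For example, 1 cluster held 2 naive and 459 peak cells and another 150 naive and 43 peak cells, so that count cannot decide. The loss of degrees of freedom is the same for every left-out tissue, yet the lowest count without another tissue was 290. Lower depth of the naive spinal dura library is argued against by its endothelial sum of 13447914 UMIs, which lay between those at onset (9474033) and peak (16258904). Thinning, after which 889 genes passed, cut all libraries to the endothelial sum of naive cranial dura (6065998 UMIs). A larger response in spinal dura and the sample handling of that library, in which 1878 of 5158 barcodes exceeded 10% mitochondrial UMIs, stay open as untested, and the pattern may be biological only as a hypothesis.

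Other results stood apart because the change differed between tissues. The interaction of Serpina3f was -4.029 and that of Fgl2 -3.44 at peak (edgeR). The B cell share moved up in brain and spinal cord and down in both dural tissues, a difference that was not tested: its log2 ratio to naive at onset was 1.01 in brain, 0.93 in spinal cord, -3.21 in cranial dura and -2.75 in spinal dura, and at peak 2.43, 0.60, -2.47 and -1.95. The brain held 3, 5 and 19 B cells at the 3 stages. The NK cell share at onset moved the same way, also not tested, with 1.59, 0.93, -1.63 and -1.28, and the naive brain held 2 NK cells. Between spinal and cranial tissues 686 endothelial genes differed in their EAE change (edgeR), a grouping that also parts the libraries with shared barcodes from the others.

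Each stage test blocks on tissue, so its real split was compared with the splits that also part as many tissues, 8 in each case, too few for a share under 0.05. For endothelium 1056 genes passed at onset (highest other 0) and 1183 at peak (highest other 0), and for border macrophages 189 at onset (highest other 9) and 576 at peak (highest other 1), each with 1 of 8 splits as large, the real one included. For dura against brain and spinal cord only 3 splits keep tissues whole, again too few, with 4296 genes in the model used for splits, a highest other of 324 and 1 of 3 as large. For endothelial peak against onset the splits decide nothing, since the real count was 0 and all 8 had to reach it. The remaining splits put both libraries of at least 1 tissue on the same side. With these included, 35 in all, the highest other was 0 and 5 in endothelium at onset and peak and 330 and 29 in border macrophages. The 330 came from the naive brain, spinal cord and spinal dura libraries against the rest. For peak against onset the highest was 686, from spinal against cranial tissues, which points to a structure of the samples. That grouping was picked from these splits, so having 1 of 3 whole-tissue splits as large (highest other 9) says nothing about chance.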

How the results depend on the processing

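The alternatives on shared barcodes, on their clusters, on the naive spinal dura cluster and on mixed sub-clusters, and all alternatives of the spinal against cranial test, are tests chosen after the results were seen. Stages were paired by tissue through the tissue block, and the labels give no replicate numbers that pair libraries in another way. Of the named genes, 14316 values under an alternative kept their direction and side of the threshold, 376 passed it newly, 1341 no longer passed and 3 changed sign. Of the gene lists the counts were 2107, 60, 70 and 1. Mean log2 ratios of immune shares moved by less than 1 SD over tissues under each alternative, although the B cell ratio at peak ranged from -1.27 to 0.36 with a tissue left out. Unless stated, the cause was not tested.

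Leaving out each tissue gave 111 to 776 genes in endothelium at onset, 106 to 886 at peak, 0 to 0 for peak against onset, 3774 to 8063 for dura against brain and spinal cord (stages included), 0 to 20 and 0 to 10 for the interactions at peak and onset, 11 to 284 and 33 to 593 in border macrophages, 0 to 170 and 0 to 91 in neutrophils at onset and peak, and 0 to 1180 for spinal against cranial tissues. Microglia without a tissue and neutrophils without cranial dura had no value, and no cluster was named lymphatic endothelial-like, so that alternative gave none.

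Without a tissue block endothelium had 0 genes at onset and 0 at peak, microglia 0 and 0, and border macrophages 6 and 27. By construction the spread between tissues then counts as error. With DESeq2 the counts were 2088 and 2275 in endothelium, 3 for peak against onset, 51 and 35 for the interactions at peak and onset, 413 and 932 in microglia, 315 in border macrophages at onset, 33 and 21 in neutrophils and 1453 for spinal against cranial tissues. With a mean of at least 20 CPM, which tests fewer genes, they were 396 and 413 in endothelium, 4187 for dura, 1 for the interaction at peak, 24 and 65 in microglia, 85 in border macrophages at onset and 1 in neutrophils at onset. With no low-count filter they were 4 for the interaction at peak, 839 and 1533 in microglia, 720 and 1289 in border macrophages and 100 and 77 in neutrophils.

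With no doublet removal 2062 genes passed in endothelium at peak, 287 and 476 in microglia, 56 and 251 in border macrophages and 2 in neutrophils at peak. With at most 5% mitochondrial UMIs the interaction at peak had 1, microglia at onset 133 and border macrophages 116 and 311, and with at least 1000 UMIs border macrophages had 119 and 283. Thinning to the shallowest library gave 0 for the interaction at peak, 95 and 279 in border macrophages and 3 in neutrophils at peak. Leiden resolution 0.5 gave 1 for endothelial peak against onset. In endothelial cells with no UMI of Ptprc, Tyrobp, Cd3e and Cd79a there were 773 genes at peak and 0 for the interaction at peak. With the clusters of shared barcodes counted as endothelial there were 142 at onset, 170 at peak and 0 for the interaction at peak, and without the cluster of most naive spinal dura endothelium 0 for the interaction at peak.

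The sign changed for Alcam in dura against brain and spinal cord, at -0.79 with all libraries, 0.14 with the clusters of shared barcodes counted as endothelial, 0.62 without cranial dura and -2.22 without spinal dura, the range over left-out tissues and stages. It also changed for Top2a in the same comparison, 1.64 with all libraries, -0.094 without brain and 3.27 without spinal cord, and for the cell cycle list in border macrophages at peak, whose median was 0.37 while camera ranked it lower, against a median of 0.82 and a higher rank with no doublet removal. Depth limits the border macrophage comparisons and the interaction at peak, whose counts were lower in thinned libraries. Why the self-test recovered fewer 4-fold changes in neutrophils (13% and 26%) than in microglia (59%) was not tested.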

Other observations

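Within single tissues, with 1 library per stage and no test, some genes differed by large ratios. In spinal cord endothelium at peak the adhesion receptor Sele had 2 counts in the naive library and 10428 at peak (ratio 4771, counting interval 1321 to 39400), and Ubd went from 0 to 10842 counts, at least 3307-fold higher against 3 counts. Gstp1, a glutathione transferase gene, went from 65.1 to 1.81 CPM. In spinal dura endothelium at peak Glycam1 was at least 1718-fold higher (0 and 6230 counts), and Edn3 went from 102 to 6.46 CPM. In cranial dura Cxcl1 went from 2.31 to 176 CPM at onset, and the transcription factor gene Zbtb16 from 132 to 15.5 CPM at peak. In spinal cord microglia at onset the immediate early gene Egr1 went from 3149 to 116 CPM and Hpgd from 519 to 10.4 CPM, while in brain microglia at peak Cxcl9 was at least 1766-fold higher (0 and 3017 counts). Cranial dura border macrophages went from 298 to 0.901 CPM of the collagen-degrading protease gene Ctsk at onset, and those of spinal dura went from 504 to 4.49 CPM of Mgl2 at peak. In cranial dura neutrophils at onset Ifitm1 went from 324 to 6333 CPM and Wfdc17 from 319 to 5639 CPM.

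Less abundant immune cells also differed between libraries. Dendritic cell-like cells were 0.338%, 3.38% and 7.38% of the immune cells of brain at the naive, onset and peak stages and 0.282%, 4.97% and 4.10% in spinal cord, against 11.6%, 8.09% and 10.8% in cranial dura and 6.37%, 6.48% and 12.3% in spinal dura. Their mean log2 ratio to naive was 1.74 ± 2.33 at onset and 2.29 ± 2.21 at peak (SD, n = 4 tissues, exact sign-flip permutation p = 0.375 and 0.25). Neutrophil precursor-like cells made up 11.7%, 20.8% and 13.3% of the immune cells of cranial dura, 2.70%, 4.63% and 4.14% of spinal dura, and at most 0.376% in brain and spinal cord. ILC2-like cells were 5.90% of the immune cells of the naive cranial dura and 2.41% and 2.29% at onset and peak. In spinal dura they were 8 of 408 naive immune cells and 0 of 5288 at peak, which allows a share of up to 0.0567%.

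The spinal against cranial test and its tests below were chosen only after the result was seen. It compared the EAE change (onset and peak) in spinal cord and spinal dura endothelium with that in brain and cranial dura, and 370 genes were higher and 316 lower (edgeR, 3482 at an unadjusted p below 0.05, 685 of 686 with the same sign in both pairs of tissues). Higher were the activin gene Inhbb (3.67 ± 0.65), Upp1, Col15a1 and Igfbp3 (3.05, 2.77 and 2.23 log2), and lower were Notum (-2.26 log2), Car4 (-1.60 log2) and Vegfc (-1.64 log2). Of 12 glycolysis genes 6 were higher (camera adjusted p = 0.000124, and adjusted p = 0.468 with an estimated correlation). Other lists moved too, with a median log2 difference of 2.32 for cell cycle, 1.14 for inflammatory macrophage and -2.21 for homeostatic microglia (camera adjusted p = 0.000151, 0.0023 and 0.000151). For the barrier and Wnt target lists it was -0.34 and -0.53 (camera adjusted p = 0.0054 and 0.0038). None of these held with an estimated correlation. The count was 0 without cranial dura, 15 without brain, 363 without spinal dura and 1180 without spinal cord, so it rests on the cranial libraries. Brain and cranial dura are also the libraries that share barcodes, so the spinal against cranial difference cannot be told apart from that grouping. The test counts the onset and peak libraries of a tissue as repeats, so its p-values may be too small.

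The hypothesis that the acute phase response may be stronger in spinal than in cranial endothelium was tested on the fixed acute phase and NF-kB list. The median difference was 0.7192 for spinal cord minus brain and 0.2887 for spinal dura minus cranial dura, both above 0, and 12 of 16 members were above 0 in each pair. None of the 16 passed the edgeR test over all genes or adjusted over the list alone, and the list had a camera adjusted p = 0.023, and adjusted p = 0.706 with an estimated correlation. The hypothesis therefore rests on a direction that no single member carries past the test.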
